A study of Mus musculus with 14 samples.

How the data were processed

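Poly(A) RNA from mouse brain was sequenced on an Illumina HiSeq instrument, per the labels. The 14 libraries fall into 6 groups: adult KO2 (n = 2), adult KO3 (n = 2), adult wild type (n = 4), E19.5 KO2 (n = 2), E19.5 KO7 (n = 2) and E19.5 wild type (n = 2). Groups were taken from the sample titles, and the adult wild-type titles divide that group further into set 1 (replicates 1 and 2) and set 2 (replicates 3 and 4). The labels do not say that replicates came from separate animals, so every p-value measures the spread between these samples, which may be technical. The series description also names embryos and embryonic stem cells, which were not analysed here.

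Expression values were FPKM (fragments scaled to transcript length and to the library's mapped fragments), as deposited by the authors in 1 table with 1 column per library. The submitters' processing notes name CASAVA, TopHat2 2.1.1, Cufflinks 2.2.1 and the mm9 build. They give no role or order for these tools, and the annotation, any filter, any scaling between libraries and the use of strand are not given in the sources used here. A leftover header word in the deposited table reads FPKM for 10 of the 14 libraries. The other 4 libraries (both adult KO3 libraries and wild-type set 2) carry no such word and were taken as FPKM. Their upper quartiles were 11.1 to 12.5, against 11.8 to 13.1 in the other 10, but their low values differ. The table held 23375 genes. A further 2 entries named no gene and were left out.

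The 4 adult KO3 and wild-type set 2 libraries had been handled differently from the other 10 before deposit. In these 4, 9994 genes (42.8%) were listed at 0 in every library, 6396 of which had a value above 0 in at least 1 of the other 10. The smallest of the per-gene maxima above 0 in the 4 libraries was 1.02 FPKM. A value of 0 there may therefore be a removed low value, and such genes are described as listed at 0. The adult comparisons were for this reason also made with the sets apart, each knockout against the wild-type set handled like it: KO2 against set 1 and KO3 against set 2. This second fit was chosen after the data were seen.

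FPKM values carry no read totals. Ratios of low values between libraries did not fall on the steps that whole reads would give (at most 14.3% of genes in the fullest bin over 45 pairs of libraries), so depth is unknown and no counting interval was computed. Between 12701 and 13398 genes per library reached 1 FPKM. Pearson's r across genes between libraries of a group was 0.964 to 0.983, and 0.946 to 0.953 between libraries of the 2 adult wild-type sets. No library pair of a group shared more than 0.014% identical values among tested genes, so each library was counted as a replicate.

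Genes with at least 1 FPKM in at least 2 libraries were tested (14322 genes). Values were transformed to log2(FPKM + 1), so fold changes are on that scale and understate changes of low genes. Group means of all 14 libraries were fitted with limma 3.58.1 in R 4.3.3 (trend option, 2-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Residual degrees of freedom were 8, and 7 with the sets apart. Gene lists were fixed before the data were examined and cover imprinted clusters, cell types, brain regions, stress and metabolic pathways. Of these, 46 had at least 3 tested members and were tested in 8 comparisons with camera at a preset correlation of 0.01, adjusted over all 368 tests. An estimated correlation and fry served as further tests. At the preset correlation 87 list tests passed, against 2 with an estimated correlation (sex-linked genes in both KO7 comparisons) and 30 with fry. Counts of list members are given over all genes tested and adjusted over the list alone.

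Genes are named by a rule fixed before the data were examined. It takes all genes at the deleted regions. It takes, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold that reach a mean of 1 FPKM in 1 group and whose libraries do not overlap between groups. It takes up to 4 members with the smallest p from each list that passed and up to 2 from other lists, the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, and the 5 largest interactions each way. Genes outside it are said to have been chosen after their values were seen. Some genes that met the rule are not reported here. Symbols were matched to a RefSeq gene table of assembly GRCm38.p6 for names and gene order only: 21625 matched by symbol, 1596 by synonym and 154 not at all.

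The procedure was tested on simulated values with 200 changed genes in 5 draws per comparison. At a log2 change of 1 it recovered 62.2% of them for E19.5 KO2, 61.4% for E19.5 KO7, 79.1% for adult KO2 and 77.7% for adult KO3. At a log2 change of 0.5 it recovered 0 to 5.3% over the comparisons simulated. The simulated noise was independent and equally large in all groups, and held no difference between the adult wild-type sets. Recovery in the real adult comparisons may therefore be lower. Alternatives varied the pseudocount (0.1, 10), the filter (none, 5 FPKM), the scaling (median of ratios, quantile), the libraries in the fit, the variance model, a replicate block, a 2-fold threshold, each left-out library and the wild-type set. A further fit left out 3 libraries, below called those that stand apart. They were picked after the data were seen, by no criterion fixed beforehand, and are not established outliers. Of them, adult wild-type replicate 4 had r = 0.982 with replicate 3, and E19.5 KO2 replicate 1 had 0.980 with replicate 2. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.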

Results

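Brain transcriptomes were measured in mice produced with haploid embryonic stem cells from which imprinting control regions (differentially methylated regions, DMRs) had been deleted. KO2 animals lacked the H19-DMR and the IG-DMR, KO3 animals lacked these and the Rasgrf1-DMR, and KO7 animals lacked the Nespas, Grb10, Igf2r, Snrpn, Kcnq1, Peg3 and Gnas DMRs. From what is known of the study, and not from the labels, KO2 and KO3 served to combine a pair of maternal genomes and KO7 a pair of paternal genomes. If so, each knockout against wild type also sets such a pair against a maternal and a paternal genome. Deletions and parental origin of the genomes then cannot be told apart. Levels are given as FPKM, mean ± SD, with n = 2 libraries per group and n = 4 for adult wild type. Fold changes are on the log2(FPKM + 1) scale, and adjusted p-values are from limma. Read depth is unknown, and each library reached 1 FPKM in 12701 to 13398 genes. The labelled stages separated strongly: 7877 of 14322 tested genes differed between adult and E19.5 wild type (2920 higher and 4957 lower in adult).

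The deleted regions are control elements rather than transcripts, so no value reads a deletion directly, and the imprinted genes beside them were examined in every library first. Rasgrf1, a guanine nucleotide exchange factor for Ras, had 12.03 and 12.75 FPKM in E19.5 wild type, 2.94 and 0.670 in KO2, and 8.25 and 8.16 in KO7. In adults it had 89.5, 100, 149 and 97.2 FPKM in wild type and 19.7 and 14.8 in KO2. It had 104 and 85.3 in KO3, the line that also carries the Rasgrf1-DMR deletion. The maternally expressed non-coding RNA H19 had 15.97 and 24.3 FPKM in E19.5 wild type, 35.003 and 38.2 in KO2, and 95.7 and 87.7 in KO7. The growth factor gene Igf2, next to H19, had 37.6 and 65.5 FPKM in E19.5 wild type, 35.1 and 38.4 in KO2, and 108 and 93.6 in KO7. In adults Igf2 had 19.4, 23.3, 19.8 and 27.9 FPKM in wild type, 19.3 and 14.4 in KO2, and 22.2 and 18.4 in KO3. Adult H19 was below 1 FPKM in both KO2 libraries (0.225 and 0.0970) and in wild-type set 1 (0.929 and 0.672), and listed at 0 in the other 4 adult libraries.

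At the IG-DMR cluster, the non-coding RNA Meg3 had 560 and 723 FPKM in E19.5 wild type, 658 and 770 in KO2, and 385 and 558 in KO7. Adult Meg3 was 649, 651, 401 and 354 FPKM in wild type, 527 and 657 in KO2, and 341 and 559 in KO3. Of 8 tested genes in the H19 and IG-DMR clusters (Igf2, Dlk1, Rtl1, Dio3, H19, Meg3, Rian and Mirg), none passed in E19.5 KO2 or either adult knockout against wild type (limma). The nearest in E19.5 KO2 was Mirg, at 20.1 ± 3.13 against 9.83 ± 1.39 FPKM (log2 change 0.96, adjusted p = 0.213). Adjusted over the list alone, 2 of the 4 maternally expressed members were higher in E19.5 KO2, and the list as a whole missed the threshold (camera adjusted p = 0.0684, and 0.046 with the sets apart).

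At the regions deleted in KO7, Cdkn1c, a maternally expressed inhibitor of cyclin-dependent kinases in the Kcnq1 domain, rose in E19.5 KO7 from 25.3 ± 1.69 to 79.2 ± 6.66 FPKM (log2 change 1.61, adjusted p = 0.000189). Zim1, a maternally expressed zinc finger gene beside Peg3, fell from 7.14 ± 0.968 to 1.57 ± 0.244 FPKM (log2 change -1.66, adjusted p = 0.0398). Values that missed the threshold were Grb10 at 28.5 ± 1.97 against 17.6 ± 2.68 FPKM (adjusted p = 0.285) and Gnas at 1043 ± 144 against 874 ± 42.4 (adjusted p = 0.708). Snrpn, at 227 ± 22.2 against 249 ± 27.3 FPKM (adjusted p = 0.876), and Ube3a (log2 change -0.44, adjusted p = 0.373) missed it too. The 12 paternally expressed genes at these regions did not move as a list (camera adjusted p = 0.982), and none passed over all genes in limma or adjusted over the list alone. Of the 10 maternally expressed genes 1 rose and 1 fell, and the list missed the threshold (camera adjusted p = 0.688).

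**Figure D1:**
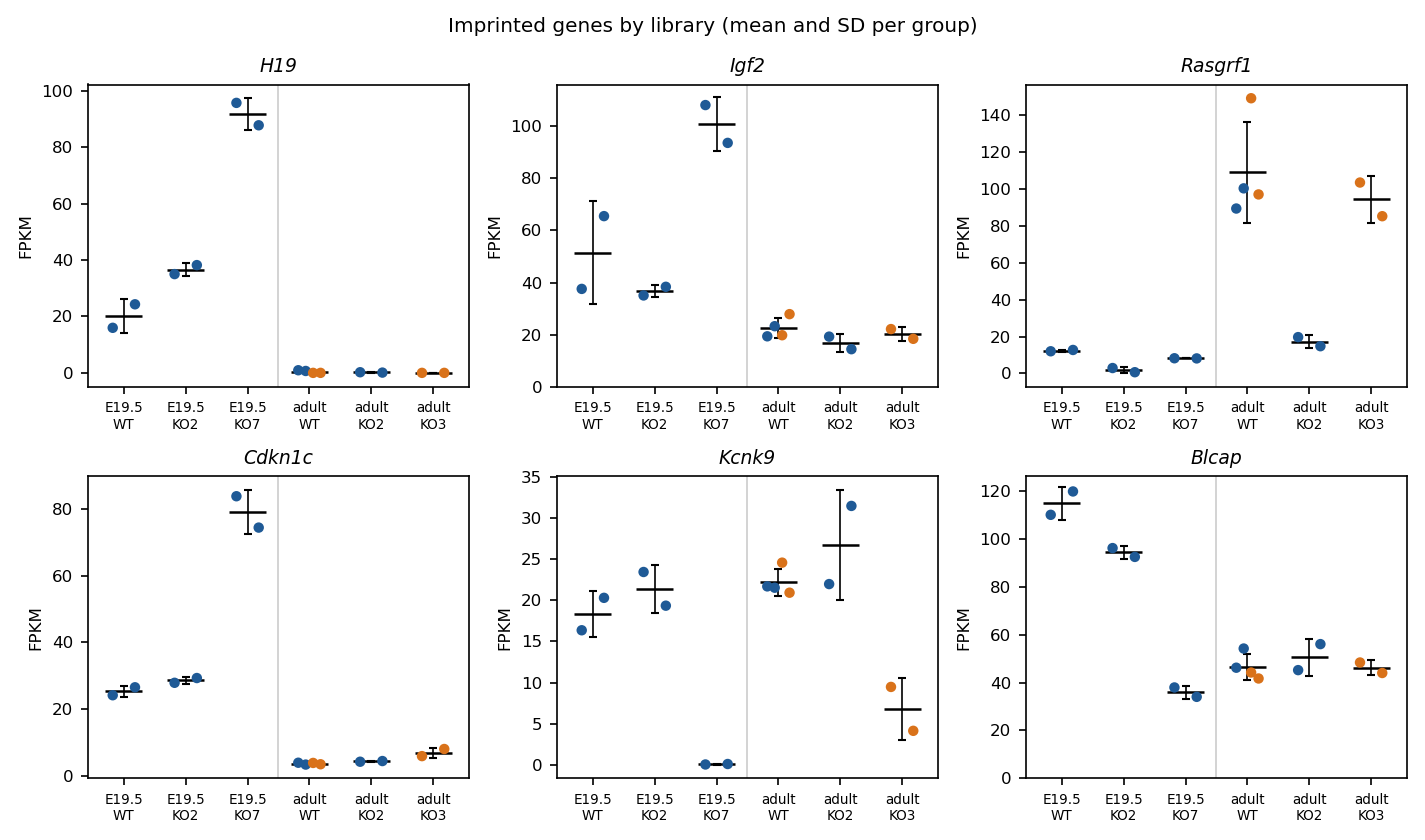
FPKM of imprinted genes in each of the 14 libraries, by group, with bars for mean ± SD; orange points mark the 4 adult libraries that list low genes at 0. Rasgrf1 lies at 14.8 and 19.7 FPKM in adult KO2 and between 85.3 and 149 in adult KO3 and wild type, and Kcnk9 lies at 0.0444 and 0.101 in E19.5 KO7.

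Sex-linked transcripts differed between the groups. Eif2s3y (23.8 ± 1.73 FPKM), Ddx3y (7.40 ± 0.460), Kdm5d (6.34 ± 1.53) and Uty (2.73 ± 0.342), all on the Y chromosome, were present in both E19.5 KO7 libraries. In the other 12 libraries they were listed at 0, apart from 0.0274 FPKM of Eif2s3y in E19.5 KO2 replicate 2 and 0.00916 of Uty in adult wild-type replicate 2. Xist, the RNA that coats the inactive X chromosome, fell in KO7 from 112 ± 8.17 to 0.0281 ± 0.0172 FPKM (log2 change -6.77, adjusted p = 0.0131). It cannot be told apart here from its antisense partner Tsix, because the use of strand is not stated. The 2 E19.5 KO2 libraries had 1.5 and 84 FPKM of Xist, and adult levels were 56.4 ± 12.2 in wild type, 37.7 ± 5.12 in KO2 and 32.6 ± 15.7 in KO3. As a list the sex-linked genes passed in KO7 (camera adjusted p = 7.14e-10), and still did with an estimated correlation (adjusted p = 0.0298). Every comparison of E19.5 KO7 with wild type is therefore also one of male-pattern against female-pattern libraries, in which sex and genotype cannot be told apart.

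The comparison of E19.5 KO2 with wild type asks what brains with the H19-DMR and IG-DMR deletions express at the end of gestation. At the preset correlation, lists of glial and endothelial genes were higher and sterol synthesis genes lower, and none of these calls held with an estimated correlation (adjusted p = 0.293 to 0.462). Fam107a, an actin-associated protein of astrocytes, rose from 1.40 ± 0.163 to 12.9 ± 1.69 FPKM (log2 change 2.53, adjusted p = 0.000844). Txnip, a thioredoxin inhibitor that limits glucose uptake, fell from 33.3 ± 3.46 to 5.08 ± 0.104 FPKM (log2 change -2.49, adjusted p = 0.000844). Rasgrf1 fell from 12.4 ± 0.503 to 1.81 ± 1.60 FPKM (log2 change -2.38, adjusted p = 0.0166). Fam107a, Txnip and Igfbp3 passed in each of the 18 settings tried, and every other gene called in this comparison was lost in at least 1 of them.

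The myelin gene Mbp rose from 12.4 ± 2.17 to 65.7 ± 33.4 FPKM (log2 change 2.23, adjusted p = 0.0276). Also higher were Ly6c1, a surface protein of endothelial cells (24.6 ± 0.0257 against 6.12 ± 0.528 FPKM, adjusted p = 0.00593) and Igfbp3, an IGF-binding protein (29.5 ± 2.34 against 9.12 ± 1.09, adjusted p = 0.000978). Aldoc, the aldolase of astrocytes, rose from 72.5 ± 9.75 to 217 ± 7.29 FPKM (adjusted p = 0.0276). Hif3a, a hypoxia-inducible factor subunit, rose from 1.03 ± 0.168 to 4.98 ± 0.312 FPKM (adjusted p = 0.00593). Ctgf, a matricellular growth factor, rose from 4.74 ± 0.540 to 16.1 ± 3.75 (adjusted p = 0.0166), and A230057D06Rik by a log2 change of 2.27 (adjusted p = 0.0359). Fabp4, a fatty acid carrier, had a mean of 2.37 FPKM in KO2 and was listed at 0 in wild type (adjusted p = 0.0276). The falls included Aplnr, the apelin receptor (1.31 ± 0.273 against 6.31 ± 0.236 FPKM, adjusted p = 0.0198), Slc22a6, an organic anion transporter (0.743 ± 0.102 against 2.70 ± 0.315, adjusted p = 0.025), and C130071C03Rik (log2 change -1.25, adjusted p = 0.0457).

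Of the fixed lists, cholesterol synthesis was lower in E19.5 KO2 (camera adjusted p = 7.14e-10; adjusted p = 0.399 with an estimated correlation), with all 13 members below wild type and a median log2 change of -0.642. None of the 13 passed over all genes in limma, and 9 were lower adjusted over the list alone. Examples are Idi1 (15.5 ± 0.152 against 30.1 ± 3.71 FPKM, adjusted p = 0.105), Sqle, a rate-limiting oxygenase of the pathway (42.5 ± 1.48 against 71.1 ± 4.64, adjusted p = 0.112). Cyp51 was at 22.9 ± 1.38 against 37.0 ± 1.90 FPKM (adjusted p = 0.101). Astrocyte markers were higher (camera adjusted p = 1.19e-08; adjusted p = 0.293 with an estimated correlation), all 10 of them above wild type, 1 passing and 7 adjusted over the list alone. S100b was at 7.60 ± 1.91 against 2.82 ± 1.16 FPKM and the filament protein Gfap at 32.8 ± 5.35 against 14.4 ± 1.04, neither passing alone. Oligodendrocyte and myelin genes were higher (camera adjusted p = 7.69e-08; adjusted p = 0.462 with an estimated correlation), 2 of 13 passing and 6 adjusted over the list alone. Clustered protocadherins of the beta family, adhesion molecules of neurons, were lower in 14 of 14 members at a median of -0.42 (camera adjusted p = 5.01e-06; adjusted p = 0.399 with an estimated correlation). None of them passed in limma, over all genes or adjusted over the list alone.

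Erythroid genes were higher in E19.5 KO2 (camera adjusted p = 1.09e-05; adjusted p = 0.399 with an estimated correlation), and 2 of 7 members passed over all genes and 2 adjusted over the list alone. Slc4a1, the red cell anion exchanger, rose from 0.367 ± 0.298 to 2.66 ± 0.0712 FPKM (adjusted p = 0.047). Lists for glucocorticoid response (camera adjusted p = 0.00227; adjusted p = 0.448 with an estimated correlation), hypoxia (0.0129; adjusted p = 0.436) and endothelial cells (0.0222; adjusted p = 0.462) were higher with 1 member passing in each. These were Sult1a1 (8.57 ± 0.360 against 2.84 ± 0.521 FPKM, adjusted p = 0.0302), the glucose transporter Slc2a1 (53.9 ± 0.449 against 19.3 ± 1.21, adjusted p = 0.0179) and Ly6c1. Adjusted over the list alone, 2, 2 and 1 members passed. Inflammation genes (camera adjusted p = 0.0027; adjusted p = 0.321 with an estimated correlation), neuron markers (0.0339; adjusted p = 0.525) and dopamine and adrenergic receptors (0.0489; adjusted p = 0.492) were higher as lists. None of their members passed in limma, and 2, 0 and 0 did adjusted over the list alone. The neuron and the dopamine and adrenergic receptor calls were lost under quantile scaling (camera adjusted p = 0.162 and 0.203), the latter also under median-of-ratios scaling (0.0586). Without the 3 libraries that stand apart (E19.5 KO2 replicate 1, adult KO3 replicate 2 and adult wild-type replicate 4) the endothelial and hypoxia calls were lost (0.104 and 0.0695).

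In all, 38 genes passed in E19.5 KO2 against wild type, 33 higher and 5 lower, and 1415 had an unadjusted p under 0.05. With quantile scaling 54 rose and 20 fell, which takes the higher share from 86.8% to 73.0%. It was 63.2% with only E19.5 libraries in the fit (230 higher, 134 lower) and 52.2% with a pseudocount of 10 (35 higher, 32 lower), so the excess of rises depends on the setting. The count was 7 without KO2 replicate 1, 18 without KO2 replicate 2, 3 without wild-type replicate 1 and 4 without wild-type replicate 2. With the adult sets apart it was 183, on the same fold changes and another spread.

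E19.5 KO7 brains, from embryos carrying 7 DMR deletions, were compared with the same wild-type libraries to ask what differs in them. Their deletions cannot be told apart here from sex pattern or from parental origin of the genomes. Imprinted genes at regions deleted in no line moved in opposite directions by parental type. All 11 maternally expressed genes lay below wild type, at a median log2 change of -1.03 (camera adjusted p = 2.85e-10; adjusted p = 0.141 with an estimated correlation), 5 of them passing and 7 adjusted over the list alone. Of the 14 paternally expressed genes 13 lay above wild type, at a median of 0.779 (camera adjusted p = 1.62e-08; adjusted p = 0.124 with an estimated correlation), 1 passing and 12 adjusted over the list alone. The potassium channel gene Kcnk9 fell from 18.3 ± 2.79 to 0.0729 ± 0.0402 FPKM (log2 change -4.16, adjusted p = 8.29e-06).

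Blcap, a regulator of apoptosis beside Nnat, fell from 115 ± 6.90 to 36.0 ± 2.77 FPKM (adjusted p = 0.000243). Trappc9, a vesicle tethering protein beside Kcnk9, fell from 21.3 ± 1.84 to 9.89 ± 0.158 (adjusted p = 0.00444), and Ago2, the catalytic Argonaute, from 13.4 ± 0.466 to 5.26 ± 1.47 (adjusted p = 0.0347). Asb4 fell from 4.27 ± 0.593 to 0.744 ± 0.0119 FPKM (adjusted p = 0.0462). Among paternally expressed genes Sgce, a sarcoglycan, rose from 14.5 ± 1.53 to 34.8 ± 4.32 FPKM (log2 change 1.21, adjusted p = 0.00647). The zinc finger gene Plagl1 was at 22.5 ± 0.801 against 8.82 ± 0.543 (adjusted p = 0.0955). H19 rose from 20.1 ± 5.89 to 91.7 ± 5.61 FPKM (log2 change 2.16, adjusted p = 0.00625), with Igf2 at 101 ± 10.3 against 51.5 ± 19.7 (adjusted p = 0.0923). Over the whole imprinted set, paternally expressed genes were higher (camera adjusted p = 7.5e-05; adjusted p = 0.349 with an estimated correlation) and maternally expressed genes lower (camera adjusted p = 0.00572; adjusted p = 0.504 with an estimated correlation). The paternal set had 1 member higher over all genes and 9 adjusted over the list alone. The maternal set had 2 higher and 6 lower, and 3 and 8 adjusted over the list alone. Kcnk9, Blcap and Cdkn1c passed in all 18 settings tried, Asb4 in 8 of 17, Zim1 in 10 of 18 and Ago2 in 12 of 18.

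**Figure D2:**
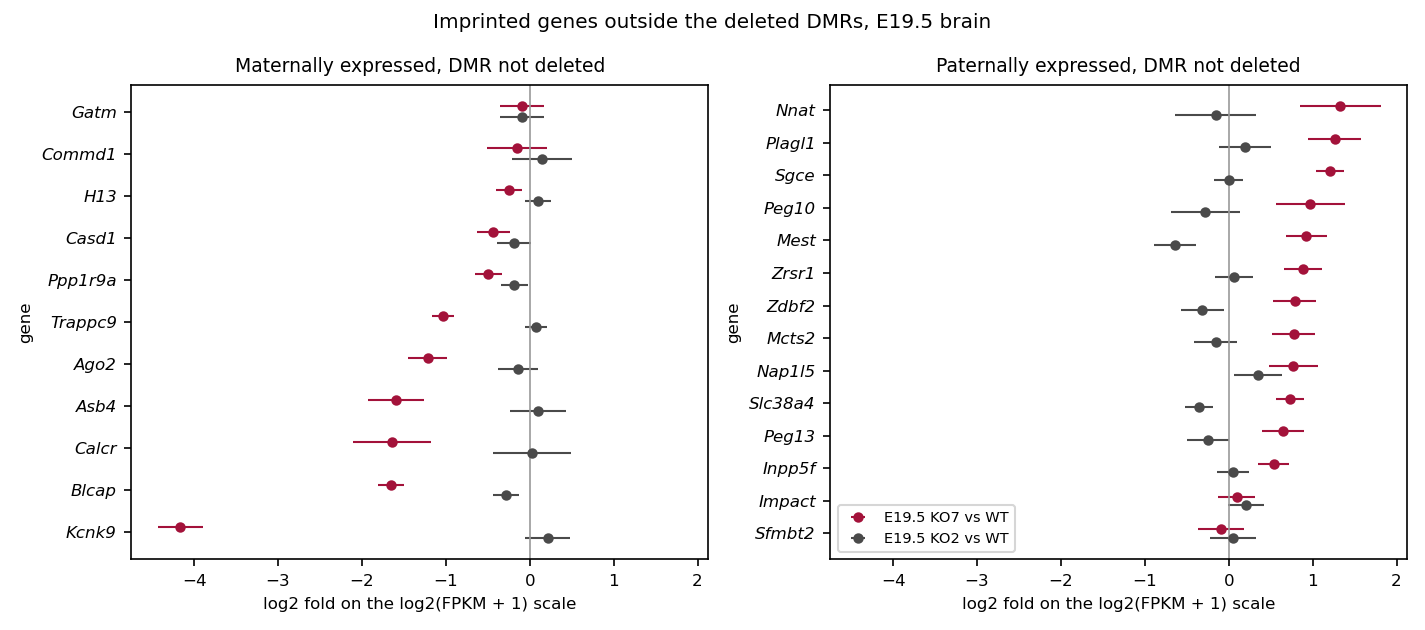
Log2 fold change of imprinted genes against wild type in E19.5 KO2 and E19.5 KO7, for genes at regions deleted in no line; each point is 1 gene and bars are standard errors of the limma fit. In KO7 the maternally expressed genes (left) centre on -1.03 and the paternally expressed ones (right) on 0.779, and Kcnk9 lies at -4.16.

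Beyond imprinted genes, Dock2, a Rac activator of blood cells, rose in E19.5 KO7 from 0.399 ± 0.0120 to 6.41 ± 0.184 FPKM (log2 change 2.40, adjusted p = 0.00569). Lrrn4 rose from 0.221 to 3.73 ± 0.185 (log2 change 1.96, adjusted p = 0.000159). Ndufa4l2, a hypoxia-inducible mitochondrial protein, rose from 1.93 ± 0.793 to 10.2 ± 2.28 FPKM (adjusted p = 0.0141), and 8430408G22Rik by a log2 change of 1.98 (adjusted p = 0.00946). The activity-dependent transcription factor Egr1 fell from 14.9 ± 1.27 to 4.22 ± 0.419 FPKM (adjusted p = 0.036). The fall of 1700048O20Rik was -2.65 on the log2 scale (adjusted p = 5.7e-05). Stfa3, a cystatin family member, fell from 2.48 ± 1.87 to 0.124 FPKM (adjusted p = 0.0465).

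Cell division genes were higher in E19.5 KO7 (camera adjusted p = 1.58e-09; adjusted p = 0.399 with an estimated correlation), 2 of 15 passing and 10 adjusted over the list alone. The mitotic kinase Cdk1 rose from 2.01 ± 0.230 to 4.62 ± 0.273 FPKM (adjusted p = 0.0437) and its partner Ccnb1 from 3.23 ± 0.302 to 7.22 ± 1.40 (adjusted p = 0.0461). Hypoxia response genes were higher (camera adjusted p = 2.29e-09; adjusted p = 0.124 with an estimated correlation), 3 of 10 passing and 8 adjusted over the list alone. Among them Slc2a1 rose from 19.3 ± 1.21 to 57.6 ± 8.55 FPKM (adjusted p = 0.00569) and the angiogenic factor Vegfa from 16.1 ± 1.35 to 34.4 ± 1.19 (adjusted p = 0.00946). Ankrd37 rose from 4.07 ± 0.261 to 13.3 ± 1.60 (adjusted p = 0.0269). Endothelial and pericyte markers were higher (camera adjusted p = 1.84e-06; adjusted p = 0.141 with an estimated correlation), 3 of 11 passing and 6 adjusted over the list alone. The pericyte genes Vtn (54.2 ± 11.6 against 21.7 ± 4.14 FPKM) and Kcnj8 (6.91 ± 0.540 against 2.48 ± 1.05) rose at adjusted p = 0.0163 and 0.0254, and Pecam1, an endothelial adhesion protein, at adjusted p = 0.0337.

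Meningeal and fibroblast genes were higher in E19.5 KO7 (camera adjusted p = 3.26e-08; adjusted p = 0.141 with an estimated correlation), 2 of 10 passing and 7 adjusted over the list alone. The matrix proteoglycan Lum rose from 1.26 ± 0.4501 to 5.67 ± 0.124 FPKM (adjusted p = 0.00675) and Fmod from 5.46 ± 2.40 to 11.5 ± 1.05 (adjusted p = 0.0448). Erythroid genes were higher at a median of 2.14 (camera adjusted p = 1.42e-07; adjusted p = 0.293 with an estimated correlation), 1 of 7 passing and 7 adjusted over the list alone. The globin Hbb-bs was at 255 ± 26.3 against 58.5 ± 19.7 FPKM (adjusted p = 0.0158), a level that near-identical globin copies make uncertain. Neural progenitor genes were higher (camera adjusted p = 0.0164; adjusted p = 0.292 with an estimated correlation), 2 of 12 passing and 3 adjusted over the list alone. The filament gene Vim rose from 101 ± 12.4 to 243 ± 17.0 FPKM (adjusted p = 0.0158), and the proneural factor Neurog2 from 2.17 ± 0.0795 to 6.33 ± 1.38 (adjusted p = 0.0306). With a pseudocount of 0.1 the progenitor list reached camera adjusted p = 0.05.

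Protocadherin beta genes were lower in 14 of 14 members in E19.5 KO7, at a median of -0.499 (camera adjusted p = 4.28e-06; adjusted p = 0.399 with an estimated correlation). None passed over all genes in limma, and 6 did adjusted over the list alone. Glutamatergic neuron genes were lower (camera adjusted p = 0.0126; adjusted p = 0.504 with an estimated correlation), with 0 passing and 3 adjusted over the list alone, among them the receptor subunits Gria2 and Grin2b. Ribosomal protein genes (camera adjusted p = 0.00118; adjusted p = 0.804 with an estimated correlation), histones (0.0135; adjusted p = 0.504) and interferon response genes (0.0184; adjusted p = 0.765) were higher as lists. None of their members passed in limma, and 0, 1 and 0 passed adjusted over the list alone. Ribosomal protein genes held 15.8% and 17.8% of the summed FPKM (small RNAs left out) in KO7, 13.5% and 14.8% in wild type, and 14.1% and 15.5% in KO2.

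In all, 145 genes passed in E19.5 KO7 against wild type, 110 higher and 35 lower, and 1993 had an unadjusted p under 0.05. With only E19.5 libraries in the fit 697 were higher and 512 lower, taking the higher share from 75.9% to 57.7%. The count was 9 without KO7 replicate 1, 22 without KO7 replicate 2, 12 without wild-type replicate 1 and 54 without wild-type replicate 2. With the adult sets apart it was 637. The KO2 and KO7 comparisons share their wild-type libraries. They had 5 genes higher in both (Tcn2, Hif3a, Igfbp7, Slc2a1 and Vwf, the last 2 known from glucose transport and endothelium), 0 lower in both and 0 opposite in limma, where independent lists would share 0.25 and 0.01. Tcn2, Igfbp7 and Vwf were chosen after their values were seen. Fold changes correlated across genes at r = 0.451, against 0.505 for simulated unchanged groups set against shared controls. The covariance was 0.0664 against 0.0416 simulated, where the wild-type libraries were shared in the same way. The simulated spread was estimated from all 14 libraries and not from the E19.5 libraries alone, so the size of the excess is uncertain. With 1 wild-type library for each knockout, a division chosen after the data were seen, r was 0.17 and 0.258 and the covariance 0.0313 and 0.0433.

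E19.5 KO7 and KO2 were also compared directly, to ask how the 2 kinds of embryo differ, with the spread still estimated from all 14 libraries. At the preset correlation, astrocyte and myelin lists were lower in KO7, with 1 member of each passing the other way, and sterol, meningeal and division lists higher. None of these calls held with an estimated correlation (adjusted p = 0.124 to 0.515). The astrocyte genes Gfap (7.06 ± 3.38 against 32.8 ± 5.35 FPKM, log2 change -2.13, adjusted p = 0.00635) and Agt, angiotensinogen (9.05 ± 6.21 against 57.9 ± 3.52, log2 change -2.70, adjusted p = 0.0302), were lower. So were Mbp (10.8 ± 1.66 against 65.7 ± 33.4 FPKM, adjusted p = 0.00709) and Fam107a (2.45 ± 1.03 against 12.9 ± 1.69, adjusted p = 0.00116). Serpina3n, an acute-phase protease inhibitor, was at 1.62 ± 0.870 against 11.2 ± 0.355 FPKM (adjusted p = 0.0168), and Lamp5 was lower by a log2 change of -1.82 (adjusted p = 0.0298). Txnip (24.8 ± 4.60 against 5.08 ± 0.104, adjusted p = 0.00116) and Slc38a5, a glutamine transporter (12.3 ± 2.23 against 2.25 ± 0.173, adjusted p = 0.0141), were higher. Rasgrf1 was also higher in KO7 (log2 change 1.84, adjusted p = 0.0176), as was Igf2 (log2 change 1.43, adjusted p = 0.0161), while H19 missed the threshold (log2 change 1.30, adjusted p = 0.052).

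The same imprinted groups parted KO7 from KO2 at E19.5. Maternally expressed genes at regions deleted in no line were lower (camera adjusted p = 7.14e-10; adjusted p = 0.141 with an estimated correlation), 5 passing and 6 adjusted over the list alone. Kcnk9 had a log2 change of -4.38 (adjusted p = 4.62e-06), Blcap of -1.37 (adjusted p = 0.00141) and Trappc9 of -1.10 (adjusted p = 0.00196). Paternally expressed ones were higher (camera adjusted p = 6.01e-09; adjusted p = 0.124 with an estimated correlation), 3 passing and 11 adjusted over the list alone. Mest, a hydrolase gene, was at 98.4 ± 21.9 against 32.5 ± 5.94 FPKM (adjusted p = 0.0109). Cdkn1c was higher by 1.44 (adjusted p = 0.000575). The union lists of imprinted genes passed in both directions (camera adjusted p = 0.000624 for maternal and 0.00159 for paternal; adjusted p = 0.436 and 0.399 with an estimated correlation). Of the maternal union 1 was higher and 6 lower, and of the paternal union 4 were higher.

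The sex-linked list passed in E19.5 KO7 against KO2 (camera adjusted p = 2.85e-10) and was the 1 list there to hold with an estimated correlation (adjusted p = 0.0298). Since Y-linked genes were listed at or near 0 in both KO2 libraries, sex and genotype cannot be told apart here either. Of the other lists, higher ones were meningeal genes (camera adjusted p = 4.53e-09; adjusted p = 0.124 with an estimated correlation; 4 passing, 7 adjusted over the list alone) and cell division (6.01e-09; adjusted p = 0.436; 3 and 10). Cholesterol synthesis (5.87e-07; adjusted p = 0.462 with an estimated correlation; 3 and 5) and hypoxia genes (0.000198; adjusted p = 0.292; 1 and 4) were higher as well. Hmgcs1, which makes the precursor of mevalonate, was at 140 ± 10.3 against 67.7 ± 4.48 FPKM (adjusted p = 0.0217) and Cyp51 at 41.6 ± 1.26 against 22.9 ± 1.38 (adjusted p = 0.0173). Neural progenitor genes were higher too (0.00516; adjusted p = 0.202 with an estimated correlation; 2 and 4), with Neurog2 (log2 change 1.45, adjusted p = 0.0109) and Nes (0.88, adjusted p = 0.0156) passing.

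Lower lists in E19.5 KO7 against KO2 were myelin (camera adjusted p = 1.98e-06; adjusted p = 0.515 with an estimated correlation; 1 member higher and 4 lower), astrocytes (0.000537; adjusted p = 0.504; 1 higher and 3 lower) and synaptic vesicle genes (0.000138; adjusted p = 0.399; 1 lower). Adjusted over each list alone, myelin had 1 higher and 8 lower, astrocytes 1 higher and 7 lower, and synaptic vesicle genes 1 lower. Against the astrocyte list's direction, the gap junction gene Gjb6 was higher (log2 change 1.03, adjusted p = 0.0176). Snap25, a synaptic fusion protein, was at 93.4 ± 1.43 against 173 ± 8.35 FPKM (adjusted p = 0.0469). Endothelial genes (camera adjusted p = 0.0227; adjusted p = 0.462 with an estimated correlation; 2 higher, 1 lower), ribosomal proteins (0.00897; adjusted p = 0.908; 0 passing) and histones (0.0235; adjusted p = 0.555; 0 passing) were higher, with 4 higher and 1 lower, 0, and 3 adjusted over the list alone. Neuron (0.0222; adjusted p = 0.504; 1 passing) and glutamatergic genes (0.0489; adjusted p = 0.57; 0 passing) were lower, with 1 and 2 adjusted over the list alone. Quantile scaling ended the neuron and glutamatergic calls (0.0657 each). Histones (0.0578) and glutamatergic genes (0.0944) missed without the 3 libraries that stand apart, and glutamatergic genes also with the sets apart (0.0532) and under median-of-ratios scaling (0.0506).

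In all, 241 genes differed between E19.5 KO7 and KO2, 141 higher and 100 lower in KO7 (2143 at an unadjusted p under 0.05). The balance turned with the pseudocount: 0.1 gave 92 higher and 118 lower, and 10 gave 359 higher and 115 lower, so that the higher share of 58.5% became 43.8% and 75.7%. The count was 31 without either KO2 library, 53 without KO7 replicate 1 and 29 without KO7 replicate 2, and 806 with the adult sets apart.

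**Figure D3:**
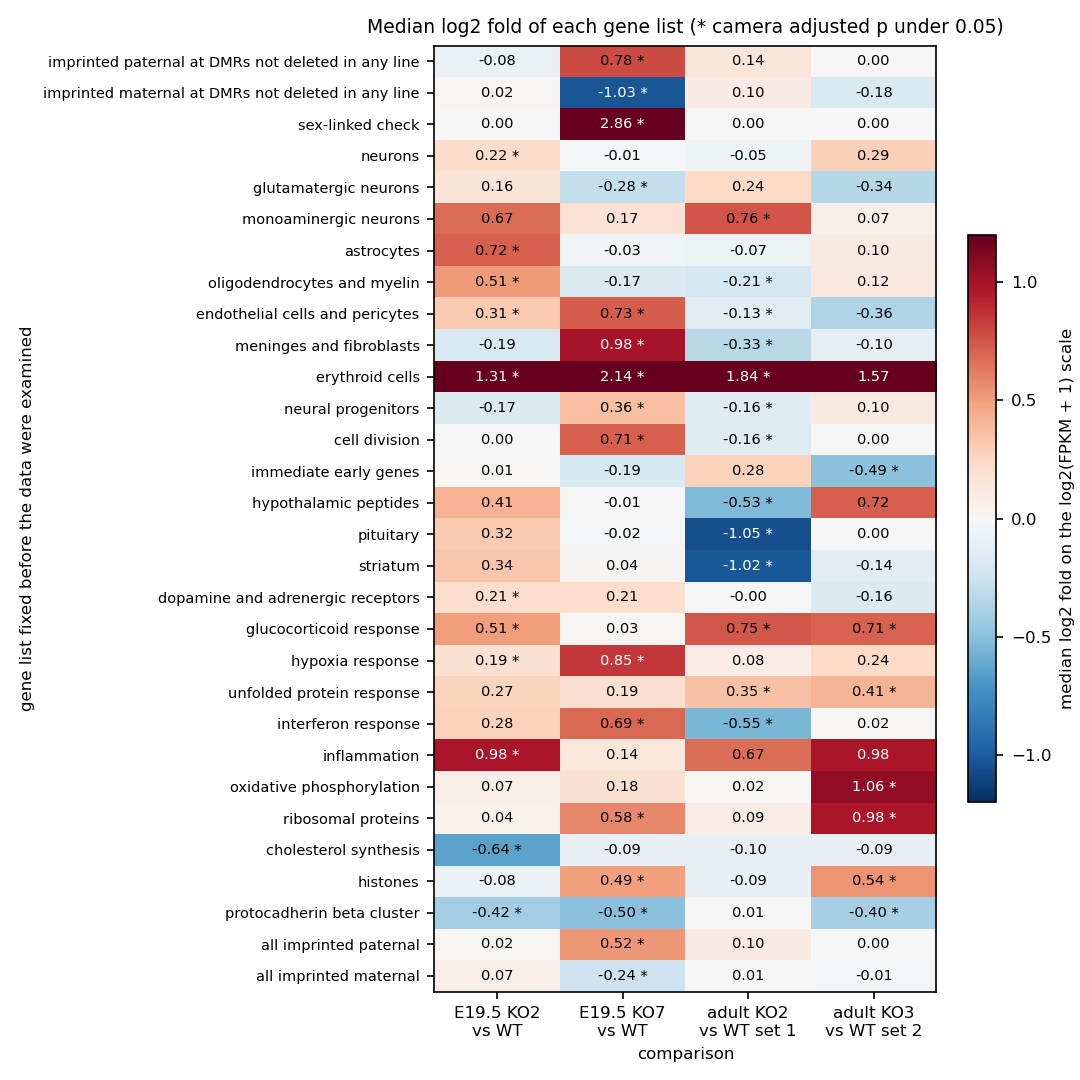
Median log2 change of the members of each fixed gene list, E19.5 columns from the 6-group test and adult columns against the wild-type set handled alike; an asterisk marks camera adjusted p under 0.05 at the preset correlation. Cholesterol synthesis stands at -0.642 in E19.5 KO2 and erythroid genes at 2.14 in E19.5 KO7.

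Among adult libraries, markers of the cerebellum followed the wild-type sets rather than the genotypes. Gabra6, a GABA receptor subunit of granule cells, had 0 and 0.127 FPKM in KO2 and was listed at 0 in wild-type set 1, against 47.3 and 29.1 in KO3 and 42.9 and 59.1 in set 2. The Purkinje cell gene Pcp2 had 0.967 and 6.54 FPKM in KO2, 0 and 0.535 in set 1, 189 and 372 in KO3, and 162 and 155 in set 2. The 2 wild-type sets differed in 2990 genes (980 higher and 2010 lower in set 2). Whether the same parts of the brain were taken from every adult is not given in the sources used here. Region and genotype cannot be told apart in adult comparisons of regional lists such as cerebellum, striatum, hypothalamus and pituitary. Adult knockouts are therefore given against all 4 wild-type libraries and, beside that, against the set handled alike. The cerebellum list was lower in KO2 (camera adjusted p = 1.77e-06; adjusted p = 0.504 with an estimated correlation) and higher in KO3 (0.0334; adjusted p = 0.905) against all 4. With the sets apart neither call held and both directions turned, to higher in KO2 (0.0532) and lower in KO3 (0.599).

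**Figure D4:**
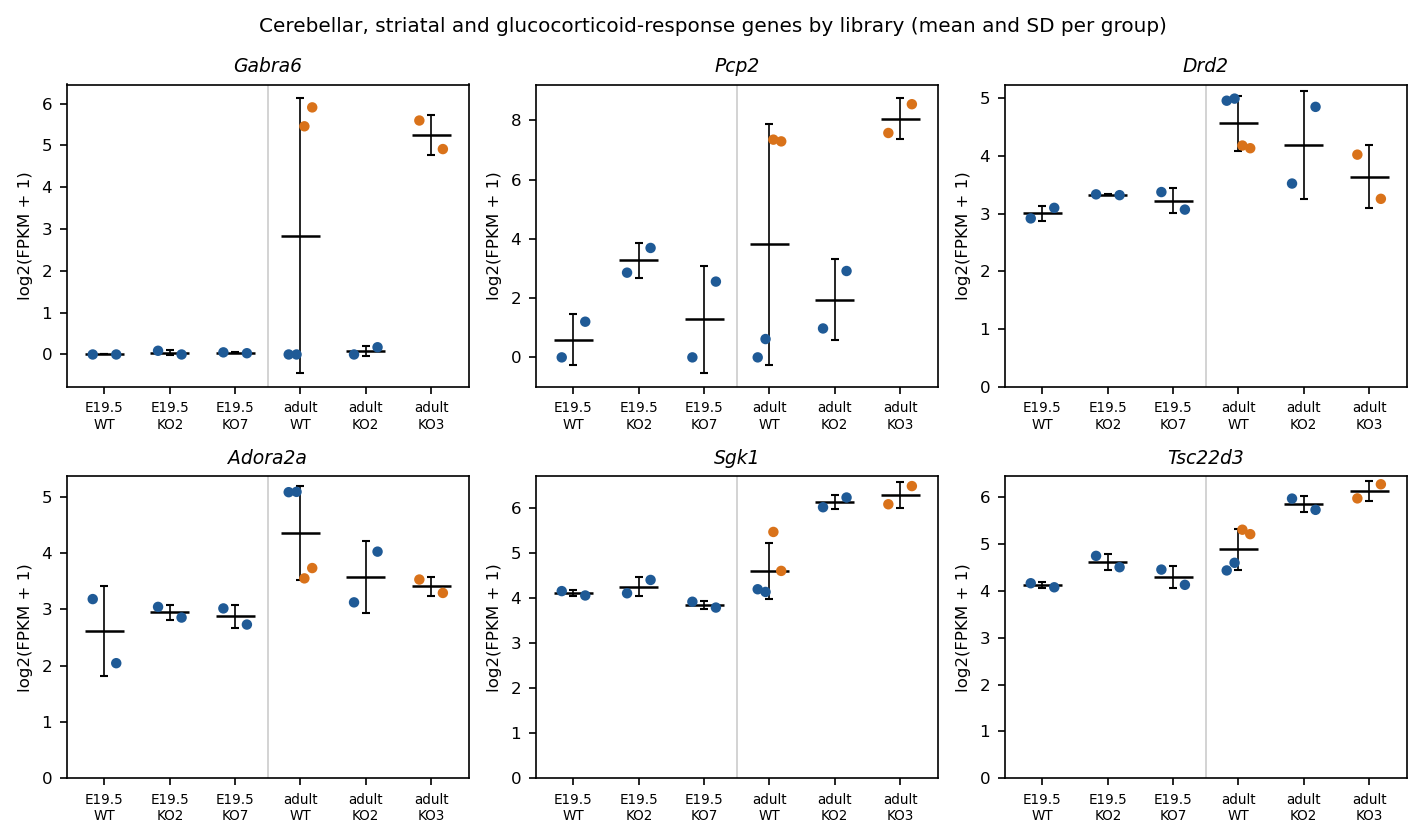
Cerebellar (Gabra6, Pcp2), striatal (Drd2, Adora2a) and glucocorticoid response genes (Sgk1, Tsc22d3) as log2(FPKM + 1) in each of the 14 libraries, by group, with bars for mean ± SD; orange points are the 4 adult libraries that list low genes at 0 and blue points the other 10. Gabra6 is at most 0.127 FPKM in adult KO2 and wild-type set 1 (blue) and at least 29.1 FPKM in adult KO3 and set 2 (orange).

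Adult KO2 brains were compared with adult wild type to ask which differences accompany the H19-DMR and IG-DMR deletions in grown animals. Rasgrf1 fell from 109 ± 27.2 to 17.3 ± 3.49 FPKM (log2 change -2.58, adjusted p = 0.00666; -2.41 and adjusted p = 0.0143 with the sets apart). Nudcd3, a dynein-associated chaperone, rose from 36.9 ± 1.77 to 65.0 ± 0.328 FPKM (log2 change 0.80, adjusted p = 0.00981). Tmed4, a cargo receptor of the early secretory pathway, rose from 39.0 ± 2.29 to 71.0 ± 4.36 (log2 change 0.85, adjusted p = 0.00971). Lct, lactase, rose from 0.133 ± 0.167 to 1.74 ± 0.411 FPKM (adjusted p = 0.019) and 2210015D19Rik from 4.33 ± 0.349 to 8.22 ± 0.475 (adjusted p = 0.0339). The fall of 2900055J20Rik, from 2.79 ± 0.847 to 0.0976 ± 0.0103 FPKM, passed at adjusted p = 0.0369. Amd1 was also called lower (log2 change -4.70, adjusted p = 0.00143) but is uncertain, since its near-identical copy Amd2 took the values: their sum was 49.4 and 44.0 FPKM in KO2 and 37.6, 36.3, 62.3 and 56.0 in wild type.

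Nudcd3, Tmed4 and 2210015D19Rik lie in a run of 40 neighbouring genes on chromosome 11, from Uqcr10 to Tbrg4 in the gene order of GRCm38.p6, that was chosen after its values were seen. Against set 1 the median log2 change of the run in adult KO2 was 0.54 (SD over genes 0.249), with 38 of 40 genes above 0, and 0.0970 over 40 flanking genes. Each KO2 library against a separate set 1 library gave 0.449 and 0.581, and the median ratio over the 35 genes with at least 5 FPKM was 1.51. The run's median was 0.145 in adult KO3 against set 2, -0.0310 in E19.5 KO2 and 0.0740 in E19.5 KO7. With the sets apart 5 of the 15 genes higher in adult KO2 lay in the run, including Nipsnap1 and Xbp1.

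**Figure D5:**
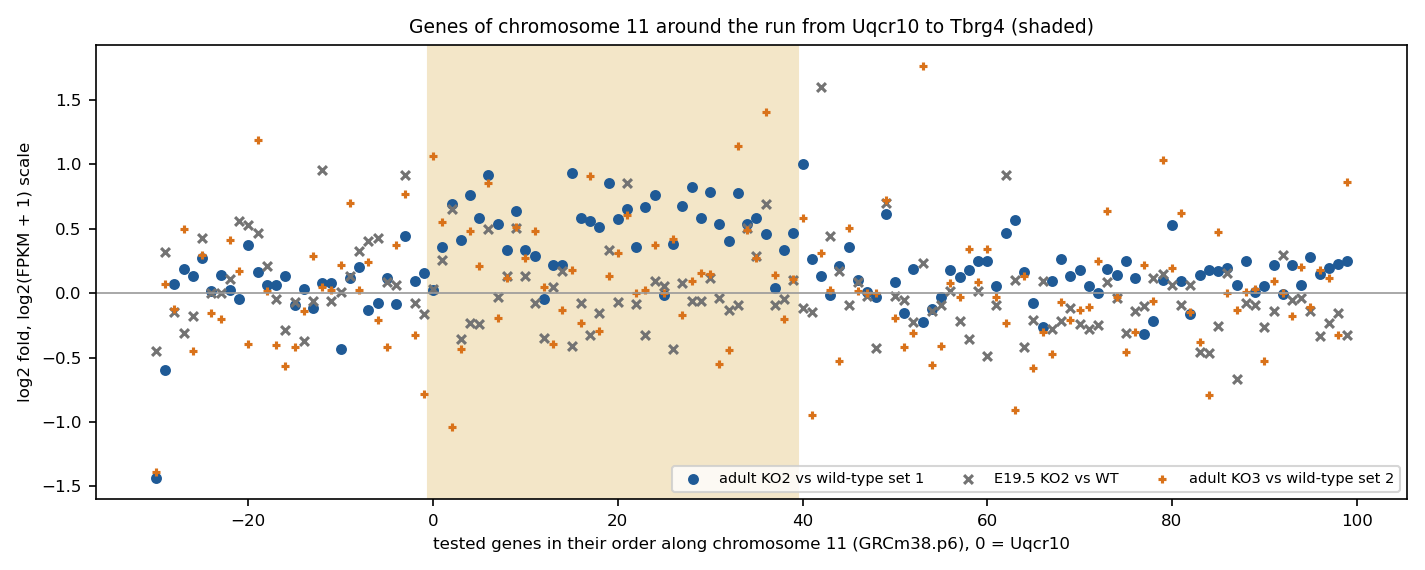
Log2 change of neighbouring chromosome 11 genes, in gene order, for adult KO2 against wild-type set 1, E19.5 KO2 against wild type and adult KO3 against wild-type set 2; the shaded run spans Uqcr10 to Tbrg4. Within the run the medians are 0.54, -0.0310 and 0.145.

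Glucocorticoid response genes were higher in adult KO2 (camera adjusted p = 2.29e-09; adjusted p = 0.141 with an estimated correlation), with 0 of 9 passing in limma over all genes and 6 adjusted over the list alone. Against set 1 the list held (camera adjusted p = 1.82e-11; adjusted p = 0.177 with an estimated correlation). Against that set 2 members rose, the kinase gene Sgk1 (log2 change 1.96, adjusted p = 0.00837) and Tsc22d3, the glucocorticoid-induced leucine zipper (1.33, adjusted p = 0.00729). Sgk1 had 63.4 and 73.8 FPKM in KO2, 17.3 and 16.5 in set 1, and 43.1 and 23.2 in set 2. Erythroid genes were higher (camera adjusted p = 5.43e-10; adjusted p = 0.179 with an estimated correlation; 0 passing and 6 of 7 adjusted over the list alone), and 4.88e-06 with the sets apart. Striatal genes were lower (camera adjusted p = 8.02e-08; adjusted p = 0.399 with an estimated correlation; 0 passing and 0 adjusted over the list alone). Against set 1 all 9 striatal genes were lower adjusted over the list alone, at a median of -1.02 (camera adjusted p = 7.18e-12; adjusted p = 0.25 with an estimated correlation). Adora2a, an adenosine receptor gene, was at 7.73 and 15.3 FPKM against 32.9 and 33.1.

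Endothelial genes were lower in adult KO2 (camera adjusted p = 4.93e-05; adjusted p = 0.222 with an estimated correlation; 0.00584 with the sets apart). The tight junction gene Cldn5 was at 14.5 ± 3.37 against 25.6 ± 7.63 FPKM. Unfolded protein response genes were higher (camera adjusted p = 0.04; adjusted p = 0.564 with an estimated correlation; 0.000678 with the sets apart). Among them Xbp1, which lies in the chromosome 11 run, rose against set 1 by 0.93 (adjusted p = 0.0272). Ribosomal protein (0.00199; adjusted p = 0.83 with an estimated correlation) and oxidative phosphorylation genes (0.0194; adjusted p = 0.706) were higher against all 4 wild-type libraries but not with the sets apart (0.993 and 0.824). Ribosomal protein genes held 9.84% and 10.4% of summed FPKM in KO2, 10.06% and 10.05% in set 1, 4.96% and 5.87% in set 2, and 8.28% and 12.52% in KO3. Protocadherin beta (0.0194; adjusted p = 0.626 with an estimated correlation) and pluripotency genes (0.0334; adjusted p = 0.399) were lower and microglial genes (0.0452; adjusted p = 0.91) higher against all 4, and not with the sets apart (0.644, 0.205 and 0.248, the microglial list then lower). In none of the lists of this paragraph did a member pass against all 4 in limma, over all genes or adjusted over the list alone, and quantile scaling ended the unfolded protein response call (0.0803).

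Against all 4 wild-type libraries 7 genes passed in adult KO2, 4 higher and 3 lower (672 at an unadjusted p under 0.05), and against set 1 with the sets apart 22 passed, 15 higher and 7 lower. With only adult libraries in the fit 2 passed, 0 higher and 2 lower. The limma count was 0 without KO2 replicate 1 (365 unadjusted) and 0 without KO2 replicate 2 (478 unadjusted).

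Adult KO3 brains, which also carry the Rasgrf1-DMR deletion, were compared with all 4 wild-type libraries. Lists for glucocorticoid response, protein folding and respiration were higher at the preset correlation, and none held with an estimated one (adjusted p = 0.399 to 0.504). Sgk1 rose from 25.0 ± 12.4 to 77.3 ± 15.4 FPKM (log2 change 1.68, adjusted p = 0.0123) and Tsc22d3 from 29.7 ± 9.01 to 69.4 ± 10.4 (log2 change 1.24, adjusted p = 0.0129). Atf4, an integrated stress response factor, rose from 48.5 ± 3.96 to 86.5 ± 12.8 FPKM (adjusted p = 0.012). The chaperone gene Hsp90aa1 rose from 402 ± 81.9 to 799 ± 149 (adjusted p = 0.0152). With only adult libraries in the fit no gene passed, and replicate 2 differed most from wild type. Rasgrf1 was at 94.5 ± 12.9 against 109 ± 27.2 FPKM and did not pass.

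Genes of this paragraph are given against all 4 wild-type libraries, where set 1 carried little or none of the cerebellar markers found in KO3. Region and genotype cannot be told apart for cerebellar genes among them. The largest rises in adult KO3 included Gng13, a G protein subunit (351 ± 227 against 78.3 ± 37.0 FPKM, adjusted p = 0.0168), and Cebpb, a transcription factor of inflammation (11.9 ± 9.46 against 1.86 ± 0.263, adjusted p = 0.0121). Nfkbia, the NF-kappaB inhibitor (50.8 ± 38.7 against 11.9 ± 1.92 FPKM, adjusted p = 0.0145), and the transcription factor gene Maff (log2 change 2.00, adjusted p = 0.0214) were higher too. The SDs of Gng13, Cebpb and Nfkbia are large beside their means, so the KO3 libraries differed widely in these genes. Pvalb, a calcium buffer of interneurons and Purkinje cells, was at 361 ± 161 against 103 ± 60.5 FPKM (adjusted p = 0.0249). Chchd2, a mitochondrial protein, was at 166 ± 70.4 against 45.5 ± 17.4 (adjusted p = 0.012) and Sh3bgr at 9.69 ± 2.67 against 2.03 ± 1.81 (adjusted p = 0.0193). Hba-a1, an alpha globin with a near-identical copy and so uncertain, was at 636 ± 226 against 104 ± 92.5 FPKM (adjusted p = 0.0228). The largest falls included the somatostatin receptor gene Sstr4 (2.09 ± 1.61 against 9.78 ± 1.86 FPKM, log2 change -1.89, adjusted p = 0.012) and Kcnk9 (6.80 ± 3.77 against 22.2 ± 1.63, log2 change -1.66, adjusted p = 0.012). Pcdh1, a protocadherin (9.93 ± 6.56 against 29.4 ± 3.35 FPKM, adjusted p = 0.0129), and Ralgps1, a Ral exchange factor (3.83 ± 2.78 against 11.7 ± 1.07, adjusted p = 0.012), also fell. Rmrp, the RNA of a ribonuclease, was lower (adjusted p = 0.0478) but missed with the sets apart (0.102).

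Among lists in adult KO3, oxidative phosphorylation was higher (camera adjusted p = 0.000109; adjusted p = 0.504 with an estimated correlation), 3 of 15 passing and 7 adjusted over the list alone. The sets apart gave 10 and 13 (camera adjusted p = 4.59e-07). Cycs, cytochrome c, rose from 38.8 ± 2.81 to 57.0 ± 3.71 FPKM (adjusted p = 0.0152). Ribosomal proteins were higher (0.000271; adjusted p = 0.726 with an estimated correlation), 2 passing and 5 adjusted over the list alone, such as Rps6 at 340 ± 75.3 against 208 ± 24.2 FPKM (adjusted p = 0.0317). The oxidative phosphorylation, ribosomal and heat shock calls were lost under quantile scaling (0.0562, 0.0748 and 0.091), and the ribosomal call also without the 3 libraries that stand apart (0.351). Glucocorticoid response genes were higher (camera adjusted p = 0.000697; adjusted p = 0.399 with an estimated correlation; 0.015 with the sets apart), 4 of 9 passing and 6 adjusted over the list alone. Unfolded protein response genes were higher (0.00126; adjusted p = 0.399 with an estimated correlation; 0.0148 with the sets apart), 3 of 9 passing and 7 adjusted over the list alone. The chaperone gene Hspa5 was at 170 ± 18.9 against 105 ± 22.4 FPKM (adjusted p = 0.0269). Heat shock genes were higher (0.00395; adjusted p = 0.459 with an estimated correlation), 4 of 8 passing and 4 adjusted over the list alone. Erythroid genes (0.0459; adjusted p = 0.686 with an estimated correlation; 2 of 7 passing) and inflammation genes (0.0489; adjusted p = 0.462; 1 of 4 passing) were higher. Adjusted over the list alone, 4 erythroid and 2 inflammation genes passed, and the heat shock, erythroid and inflammation lists missed with the sets apart (0.0522, 0.0532 and 0.214).

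Against all 4 wild-type libraries 2114 genes passed in adult KO3, 1102 higher and 1012 lower, and 4780 had an unadjusted p under 0.05. With the sets apart 3164 passed, 1990 higher and 1174 lower, and 1661 were common to both fits. With quantile scaling 865 rose and 1169 fell, taking the higher share from 52.1% to 42.5%. The SD of log2 differences from set 2 over 9372 genes was 0.759 for replicate 2 and 0.367 for replicate 1. Without replicate 2 the limma count was 0 (1864 at an unadjusted p under 0.05), and without replicate 1 it was 4491. It was also 0 with only adult libraries in the fit (3575 unadjusted) and without the 3 libraries that stand apart (2287 unadjusted), and 1 with each wild-type set averaged into 1 sample.

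Adult KO3 and KO2 were compared with each other to ask what may go with the additional Rasgrf1-DMR deletion. The KO3 libraries were handled like wild-type set 2 and the KO2 libraries like set 1. Handling and region therefore cannot be told apart from genotype in the direct comparison. With the sets apart, none of the 7 genes named in this paragraph passed. Rasgrf1 was higher in KO3 (log2 change 2.39, adjusted p = 0.0194; 2.05 and 0.0649 with the sets apart). Sstr4 was lower (log2 change -1.95, adjusted p = 0.0322, and 0.0872 with the sets apart), as was Kcnk9 (-1.90, adjusted p = 0.0206, and 0.0649 with the sets apart). Also lower were Slc24a4, a sodium-calcium exchanger (4.30 ± 2.67 against 15.5 ± 1.01 FPKM, adjusted p = 0.0247) and Dok6, an adaptor of neurotrophin receptors (11.4 ± 4.82 against 38.3 ± 0.404, adjusted p = 0.0274), at 0.0764 and 0.103 with the sets apart. The Purkinje cell gene Car8 (32.9 ± 0.224 against 2.09 FPKM, adjusted p = 0.0426) was higher but not with the sets apart (0.249). Lists higher in KO3 were cerebellum (camera adjusted p = 2.47e-05; adjusted p = 0.564 with an estimated correlation; lower, at 0.16, with the sets apart) and heat shock (0.00137; adjusted p = 0.399). Also higher were oxidative phosphorylation genes (0.0133; adjusted p = 0.687), neurons (0.022; adjusted p = 0.504) and unfolded protein response (0.04; adjusted p = 0.564), each second value with an estimated correlation. Of these only oxidative phosphorylation held with the sets apart (9.24e-06, against 0.319 for heat shock, 0.188 for neurons and 0.762 for the unfolded protein response), and it was lost under quantile scaling (0.242) and without the 3 libraries that stand apart (0.236). Over all genes 0, 2, 0, 3 and 1 members of the 5 lists passed in limma, and 6, 3, 0, 3 and 1 adjusted over the list alone. The neurofilament gene Nefm was at 185 ± 38.5 against 63.3 ± 5.22 FPKM (adjusted p = 0.0247, and 0.0887 with the sets apart).

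In all, 898 genes differed between adult KO3 and KO2, 345 higher and 553 lower (4418 at an unadjusted p under 0.05), and 7 once each was set against its own wild-type set, 7 higher and 0 lower. The count was 3 without KO2 replicate 1, 1 without KO2 replicate 2, 3442 without KO3 replicate 1 and 1 without KO3 replicate 2. With only adult libraries in the fit it was 1.

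The mean of adult KO2 and KO3 was also set against wild type, and 1 gene passed. Nme7, a nucleoside diphosphate kinase family member, was higher (log2 change 1.02, adjusted p = 0.0395; 2507 genes at an unadjusted p under 0.05) and was chosen after its values were seen. Nme7 had 49.7 and 49.8 FPKM in KO3 and 21.6 and 16.7 in KO2, against 14.9, 18.3, 12.4 and 13.8 in wild type. Its call rests mainly on KO3 (log2 change 1.69, adjusted p = 0.0015), with KO2 at 0.35 and not passing. A total of 405 genes passed with the sets apart, 364 higher and 41 lower. Under median-of-ratios or quantile scaling 0 genes passed in limma (2679 and 2533 unadjusted), as with only adult libraries in the fit (1546 unadjusted). The count was 1988 without KO3 replicate 1, 0 without KO2 replicate 1 (1792 unadjusted), 0 without KO2 replicate 2 (1728 unadjusted), 3 without wild-type replicate 2 and 2 without wild-type replicate 4. Nme7 itself did not pass without wild-type replicate 1, 3 or 4, without KO3 replicate 2, without either KO2 library or with the replicate block. Glucocorticoid response genes were higher (camera adjusted p = 3.78e-07; adjusted p = 0.209 with an estimated correlation), 0 of 9 passing in limma and 8 adjusted over the list alone. Against own sets 4 passed, among them Sgk1 (log2 change 1.60, adjusted p = 0.00319). Lists for ribosomal proteins (1.71e-05; adjusted p = 0.653), oxidative phosphorylation (2e-05; adjusted p = 0.462), erythroid cells (2.25e-05; adjusted p = 0.399), unfolded protein response (0.000271; adjusted p = 0.399), inflammation (0.0211; adjusted p = 0.399) and heat shock (0.0334; adjusted p = 0.564) were higher, each second value with an estimated correlation. Striatal genes (0.00213; adjusted p = 0.653 with an estimated correlation) and protocadherin beta genes (0.0093; adjusted p = 0.564) were lower. No member passed over all genes in limma, adjusted over the list alone 5 erythroid and 5 unfolded protein response genes did, and all 8 of these lists held with the sets apart, at 8.17e-07 to 0.0448. Quantile scaling ended the heat shock (0.296) and protocadherin beta calls (0.139), and leaving out the 3 libraries that stand apart ended the ribosomal (0.0734) and protocadherin beta calls (0.181).

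The KO2 difference from wild type was tested between stages as an interaction. Fam107a (2.54, adjusted p = 0.0126) and Igfbp3 (1.497, adjusted p = 0.038) had a larger difference at E19.5, and Txnip a lower one (-3.21, adjusted p = 0.00223). Adult Fam107a was at 101 ± 11.1 FPKM in KO2 and 102 ± 19.9 in wild type, Igfbp3 at 4.66 ± 0.858 and 4.25 ± 0.155, and Txnip at 12.7 ± 0.758 and 7.41 ± 1.60. Only these 3 genes passed (1027 at an unadjusted p under 0.05), and 9 did with the sets apart. The count was 1 without either adult KO2 library, 2 without adult wild-type replicate 3 or 4, 2 without E19.5 KO2 replicate 1, 7 without E19.5 KO2 replicate 2 and 1 without either E19.5 wild-type library.

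Lists that passed in no comparison against all 4 wild-type libraries, with the smallest camera adjusted p over the 8 comparisons, were maternally expressed genes at the regions deleted in KO2 (0.0535, in the interaction) and in KO7 (0.634), paternally expressed genes at the same regions (0.181 and 0.508), GABAergic neurons (0.0648), monoaminergic neurons (0.0876), choroid plexus (0.236), cortex and hippocampus (0.111), thalamus and midbrain (0.139), hypothalamic peptides (0.0644), pituitary (0.133), serotonin receptors (0.0786), immediate early genes (0.168), insulin-like signalling (0.33), and DNA methylation and imprint maintenance (0.0863). The maternally expressed list at the regions deleted in KO2 did pass in the interaction with the sets apart (0.015; adjusted p = 0.451 with an estimated correlation; 4 of 4 members above 0) and under quantile scaling (0.02), and in E19.5 KO2 with the sets apart (0.046). It missed in the interaction under median-of-ratios scaling (0.0841), with a pseudocount of 0.1 (0.196) and without the 3 libraries that stand apart (0.0707). GABAergic genes passed with a pseudocount of 0.1, higher in E19.5 KO2 (0.0428) and lower in KO7 against KO2 (0.0217), and likewise without the 3 libraries that stand apart (0.0472 and 0.0393). Without these 3, choroid plexus genes were higher in adult KO3 (0.0483), and DNA methylation genes lower in adult KO3 (0.0274) and in KO3 against KO2 (0.0393). In the interaction, hypothalamic peptides passed with a pseudocount of 0.1 (0.0259) and with the sets apart (0.01), and the pituitary list with the sets apart (0.00231). None of the 9 mitochondrially encoded genes was among the genes listed, so that list has no value.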

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

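The interaction tests in this part were planned, and the tests of a shift toward adult expression were chosen only after that result was seen. Of 53 groups of 4 adult wild-type values, 1 held a library far from the others, where chance would give about 1 group in 20. For Rmrp, replicate 2 had 265.9 FPKM against 29.5, 34.5 and 60.5 in the other adult wild-type libraries, a gap of 0.869 of the whole range.

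Against wild type, the KO2 difference at E19.5 departed from the KO2 difference in adults for 3 genes (limma interaction). Fam107a was higher in both E19.5 KO2 libraries (interaction 2.54, adjusted p = 0.0126), as was Igfbp3 (1.497, adjusted p = 0.038), and Txnip was lower in both (-3.21, adjusted p = 0.00223). Over 23 settings Fam107a passed in 15, Igfbp3 in 10 and Txnip in 22. Among gene lists, the difference was more positive at E19.5 for myelin (camera adjusted p = 5.08e-07, median 0.488, 12 of 13 members above 0), astrocytes (1.16e-06, median 0.686), endothelial cells (1.98e-06, median 0.571), striatum (4.2e-06, median 0.834), neurons (0.00252, median 0.295) and synaptic vesicle genes (0.0344, median 0.146). It was more negative for cholesterol synthesis (1.1e-07, median -0.707, 0 of 13 above 0) and protocadherin beta genes (0.024, median -0.358). None of these list calls held with an estimated correlation (adjusted p from 0.141 for endothelial cells to 0.655 for the cerebellum list). The cerebellum list was called too (0.00074, median 1.33), and with the sets apart its direction turned (adjusted p = 0.888), so that it followed the wild-type sets. Neurons (0.0533) and synaptic vesicle genes (0.168) were also lost with the sets apart, and the other 6 lists passed, with striatum at 1.69e-07 and cholesterol synthesis at 0.000906. Of these the protocadherin beta call was lost with a pseudocount of 0.1 (0.0529). Striatal genes were 9 of 9 lower in adult KO2 against set 1 and centred on 0.34 at E19.5.

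To ask whether E19.5 KO2 departed from wild type toward adult expression, its difference was set against the adult minus E19.5 wild-type difference over 9693 genes, with separate wild-type libraries on each side. The correlation across genes, which are not independent replicates, was 0.348 and 0.363, against 0.109 and 0.04 for KO7. A single KO2 library is argued against as the whole cause, since each library alone gave at least 0.262. Without the astrocyte and myelin lists the lower value was 0.335. This cannot decide on a glial source, since 9670 of the 9693 genes stayed in and other glial genes may be among them. A more mature brain in KO2 may account for the shift and cannot be told apart from other sources: progenitor genes had a median of -0.174 but cell division genes one of 0, and a difference in age or dissection between litters is not recorded. A biological effect of the deletions or of parental origin stays open and untested.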

How the results depend on the processing

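The fits with the wild-type sets apart, without genes listed at 0 in 4 adult libraries, without small RNAs and without the 3 libraries that stand apart were chosen after the data were seen; all others were planned. Depth is unknown and limits what can be said of low genes. Over 32 settings, of 886 pairs of a named gene and a comparison, the 186 that passed at first gave 2518 values that passed again in the same direction, 1015 that no longer passed and 0 that reversed (limma). Pairs that did not pass at first gave 13322 unchanged verdicts, 402 new passes, 752 sign changes without a pass, and 1 reversal. That 1 was Slc22a3, adult KO2 and KO3 together vs WT, at 0.445 with wild-type set 2 only (adjusted p = 0.0475). The cause was not tested for the counts that follow, except where fewer libraries or genes enter and in the E19.5 fits described next. Setting the adult wild-type sets apart, or fitting E19.5 libraries alone, left the E19.5 fold changes as they were. These counts therefore moved through the estimate of the spread.

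Counts are of genes passing, of 38 for E19.5 KO2, 145 for E19.5 KO7, 241 for E19.5 KO7 against KO2, 7 for adult KO2, 2114 for adult KO3, 898 for adult KO3 against KO2, 1 for both adult knockouts together, 3 for the interaction and 87 list calls. A pseudocount of 0.1 gave 83 for E19.5 KO7, 3 for adult KO2, 2 together and 5 for the interaction, and one of 10 gave 67, 377 and 474 in the E19.5 comparisons and 4 together. With no filter the counts were 90 for E19.5 KO2, 30 for adult KO2, 1375 for adult KO3, 7 together and 25 for the interaction, and with 5 FPKM 25 for E19.5 KO2 and 4 for adult KO2. Quantile scaling gave 74, 242 and 462 at E19.5 and 0 together (2533 unadjusted), and median-of-ratios scaling 0 together (2679 unadjusted). Same-stage libraries alone gave 364, 1209 and 1539 at E19.5, 2 for adult KO2, 0 for adult KO3 (3575 unadjusted), 1 for adult KO3 against KO2 and 0 together (1546 unadjusted). Without the trend option 3 passed together. A 2-fold threshold left 85, 123, 4, 263 and 244 for E19.5 KO7, E19.5 KO7 against KO2, adult KO2, adult KO3 and adult KO3 against KO2.

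The labels tie the replicate numbers to no litter, batch or day. Correlations across genes of same-numbered deviations between groups were -0.288 to -0.087 at E19.5 and 0.032 to 0.233 in adults, where 5 of 6 pairs of groups were above 0.1. Not every pair being above it, the numbers were not taken to pair the samples, and some pairing in adults is not excluded. A replicate block gave 7, 56 and 121 at E19.5, 2 for adult KO2, 165 for adult KO3 against KO2, 0 together (2247 unadjusted), and kept adult KO3 (1558) and the interaction (2) within 1.5 times.

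Wild-type set 1 only gave 21 for adult KO2, 4140 for adult KO3 and 1267 together, and set 2 only 1550 for adult KO2 and 1417 together. Each set averaged into 1 sample gave 1, 1 and 0 (1492 unadjusted together). With the sets apart the counts were 183, 637 and 806 at E19.5, 22 for adult KO2, 7 for adult KO3 against KO2, 405 together and 9 for the interaction. Without the 3 libraries that stand apart they were 14, 96 and 57 at E19.5, 0 for adult KO3 (2287 unadjusted), 1 for adult KO3 against KO2, 3 together and 0 for the interaction (994 unadjusted). An estimated correlation left 2 list calls and fry 30. The robust option, genes at 0 left out and small RNAs left out moved no count by more than 1.5 times.

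Leaving out each library in turn, a lone remaining library being assumed to vary like the other groups, gave 3 to 18 for E19.5 KO2, 9 to 54 for E19.5 KO7, 29 to 53 for E19.5 KO7 against KO2, 0 to 9 for adult KO2, 0 to 4491 for adult KO3, 1 to 3442 for adult KO3 against KO2, 0 to 1988 together and 1 to 7 for the interaction. The lowest adult counts in limma were 0 without either KO2 library (365 and 478 unadjusted) and 0 without KO3 replicate 2 (1864 unadjusted), and 0 together without either KO2 library (1792 and 1728 unadjusted).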

Other observations

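All tests in this part were chosen after the data were seen, except the count over the 35 splits of the adult libraries and the gene lists themselves. The count over 100 splits was added later, and what it would show was set down before its result was known. With each adult knockout set against its own wild-type set, further lists passed. In adult KO2 the pituitary list was lower (camera adjusted p = 0.000997; adjusted p = 0.229 with an estimated correlation; 0 of 4 passing in limma and 2 adjusted over the list alone), with the hormone genes Prl at 2.13 and 8.48 FPKM against 11.04 and 20.4, and Gh at 0.672 and 5.07 against 6.95 and 10.6. Hypothalamic peptide genes were lower (0.0116; adjusted p = 0.737), as were interferon response (0.0169; adjusted p = 0.737), meningeal (0.00413; adjusted p = 0.484), cell division (0.000906; adjusted p = 0.451), progenitor (0.00905; adjusted p = 0.25) and myelin genes (0.0417; adjusted p = 0.833), each second value with an estimated correlation. None of their members passed over all genes in limma, and 2 meningeal and 2 progenitor genes passed adjusted over the list alone. Monoaminergic neuron genes were higher (0.0289; adjusted p = 0.696 with an estimated correlation), with Th, the rate-limiting enzyme of dopamine synthesis, at 20.6 and 19.998 FPKM against 2.58 and 10.8.

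In adult KO3 against set 2, histone genes were higher (camera adjusted p = 0.046; adjusted p = 0.696 with an estimated correlation; 4 of 8 passing), and protocadherin beta genes (0.0108; adjusted p = 0.655; 4 of 14 passing) and immediate early genes (0.046; adjusted p = 0.816) lower. The activity-dependent factor Npas4 was the 1 immediate early gene to pass, at 3.77 ± 2.19 against 11.5 ± 4.18 FPKM over all wild-type libraries. In adult KO3 against KO2 with the sets apart, 8 further lists passed, among them ribosomal proteins (8.62e-07; adjusted p = 0.621 with an estimated correlation) and striatum (0.00584; adjusted p = 0.655), both higher, with none of the 8 holding with an estimated correlation. In gene order, the lowest window of 40 genes lay over the clustered protocadherins of chromosome 18 in E19.5 KO2 (median -0.34), E19.5 KO7 (-0.443) and adult KO3 against set 2 (-0.379). The E19.5 comparisons share their wild-type libraries, and in adult KO2 against set 1 the lowest window lay on chromosome 10 instead (Apc2 to Map2k2, -0.142). The highest window in E19.5 KO7 ended at Igf2 on chromosome 7 (0.346). In E19.5 KO2 replicate 1, with 1.5 FPKM of Xist and Y-linked genes listed at 0, the median log2 difference of 318 X-linked genes from wild type was -0.071, against -0.062 in replicate 2 and -0.116 and -0.092 in KO7.

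The run of chromosome 11 genes raised in adult KO2 was set against 3 explanations. A difference between the processing sets is argued against, since the window picked on replicate 1 and 1 wild-type library of set 1 had a median of 0.593 in the other pair of libraries, all 4 being handled alike. A chance order of genes is argued against, since 0 of 1000 shuffles held a window as high (highest 0.215, real 0.55). An extra copy of the segment may account for it: the same 0.593 was found in libraries not used to pick the window, and 3 copies against 2 would give a ratio of 1.5, where 1.51 was measured. The run was picked on the same data, the segment's DNA was not analysed here, and a biological difference between the parents' genomes stays open and untested.

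The many genes passing in adult KO3 were weighed in the same way. Whether replicate 2 alone is the cause could not be decided. Replicate 1 and replicate 2, each against a separate set 2 library, had fold changes that correlated across 9372 genes at 0.676 or more. A deviation shared by the set 2 libraries would enter each side and could give such a correlation. A graded property of the libraries, such as RNA quality or the time before freezing, is consistent with the correlation of 0.443 between the difference of replicate 1 from set 2 and the further difference of replicate 2 from replicate 1. An origin in wild-type set 2 cannot be told apart from the genotype, since the fold changes of replicate 1 from set 1 and of replicate 2 from set 2 correlated at 0.108 and the sets also differ in cerebellar genes. A biological effect of the 3 deletions or of parental origin that is stronger in replicate 2 stays open and untested.

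For both adult knockouts together against wild type, the 8 adult libraries were divided in all 35 ways. The real split gave 0 genes in a fit of these 8 libraries (limma; 807 at an unadjusted p under 0.05; highest other count 1830), so that count decides nothing about chance. In the fit of all 14 libraries, where the real split gave 1 gene, 100 of the 210 splits into groups of 2, 2 and 4 were drawn, the real one included. Of these 32 gave at least 1, so chance cannot be excluded. The highest other count there, 2798, came from a split that follows the processing sets, as did the 1830, which points to that structure of the samples, and the highest of the remaining splits drawn gave 177. Set against their own wild-type sets, 405 genes passed.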
